A study of Mus musculus with 9 samples.

How the data were processed

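RNA from whole hearts was extracted with Trizol and hybridised as biotin-labelled cRNA to Affymetrix arrays, per the labels' protocols. The deposited log2 values were made with RMA, per the submitters' processing notes. The version of RMA, the probe set definitions and a genome build are not given in the sources used here. The sorted values of all 9 arrays were identical, as quantile normalization leaves them, and the values were not centred per gene. RMA compresses low values, so fold changes of weakly expressed genes are understated. The table holds no detection p and no depth, and the number of arrays limits the precision.

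The table has 21225 probe sets. In the platform annotation 20239 had 1 gene symbol, each gene with 1 probe set, and the other 986 were not listed and are unnamed here. All 20239 matched a RefSeq gene table of assembly GRCm38.p6 by gene ID, and no symbol changed. That table was used only for names. Every column of values was used. Genes were tested if at least 3 of the 9 arrays lay above the 40th percentile of all values, which kept 12597 genes and removed 7642.

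Groups came from the sample labels, which give 3 male animals per group. One linear model was fitted over all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), with 6 residual and 3.23 prior degrees of freedom, and a gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were TAC-luciferase against sham-luciferase, TAC-HDAC4-NT against TAC-luciferase and TAC-HDAC4-NT against sham-luciferase. Gene lists were tested with fry and adjusted over the 27 lists tested in each comparison. Fry tests whether the genes of a list move on balance in 1 direction, and does not compare the list with other genes. Camera with an estimated inter-gene correlation was an alternative. The TAC response score projects each heart on the changes of the 2 TAC groups' mean against sham, and was compared by an exact two-sided permutation test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

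The groups, the tests, the filter, the gene lists, the rule for named genes and the first set of other settings were fixed before the data were examined. The 28 lists covered fetal and hypertrophy genes, extracellular matrix, MEF2 targets, class IIa HDACs with MEF2 and partners, the hexosamine pathway, fatty acid oxidation, oxidative phosphorylation, glycolysis and glucose uptake, calcium handling, ion channels and gap junctions, adult sarcomere, cytokines and acute-phase genes, interferon response, unfolded protein response, immediate early genes, the circadian clock, cell cycle, and markers of macrophages, lymphocytes, endothelium, fibroblasts, smooth muscle and pericytes, atria, epicardium, adipocytes, skeletal muscle and erythroid cells. The remaining list, of sex-linked genes, was a label check and was not tested. The named genes were those with the largest change in each direction, among genes past the threshold whose groups did not overlap, leaving out predicted gene models. That is 10 and 10 for the first 2 comparisons and 5 and 5 for TAC-HDAC4-NT against sham. Added to them were up to 4 members past the threshold of each list with the smallest p (or, where none passed, up to 2), and 14 genes named whatever their values. These were Hdac4, Nr4a1, Gfpt1, Gfpt2, Ogt, Oga, Stim1, Nppa, Nppb, Myh6, Myh7, Acta1, Col1a1 and Atp2a2. Lmo4, Adm, Bnip3, Ddit4, Hk2, Pfkfb3, Plod2 and Vegfa were named after their values were seen.

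The other settings fixed then were no filter and a stricter filter at the 60th percentile, a trended and robust prior, cyclic loess scaling, array weights, only the arrays of the 2 groups compared, the replicate number as a block, the first number of the sample code as a random block, adjusted p thresholds of 0.01 and 0.10, a minimum of 1.5-fold, camera for the lists, other gene choices for the score, and leaving out each array in turn. Settings added after seeing the data were an index of clock genes or the mean of 4 atrial genes (Myl4, Myl7, Sln and Mybphl) as a covariate, and TAC-luciferase hearts 2 and 3 both left out. The clock index is the mean of 3 activator genes (Arntl, Clock and Npas2) minus the mean of 6 output genes (Dbp, Per3, Tef, Nr1d1, Nr1d2 and Cry2).

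The scripts were tested on simulated data. For TAC-HDAC4-NT against TAC-luciferase, 12597 genes were simulated with 200 changed. The test recovered 52% of those changed 1.25-fold, 92% at 1.5-fold, 98% at 2-fold and 98% at 3-fold, with 0 in the wrong direction and 9 unchanged genes called. A list shifted by 0.3 log2 units was called, and 0 of 27 unshifted lists were. The simulated genes were independent, with normal noise of the same spread in every group. They hold neither the correlation between genes nor the split within the TAC-luciferase group. These rates therefore test the scripts and are not the power of the real comparison. Chance agreement between comparisons that share arrays was taken from 100 simulations of unchanged groups.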

Results

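Gene expression was measured in whole hearts of male C57BL/6 mice on 9 Affymetrix arrays, in 3 groups of 3 hearts. All mice received an adeno-associated virus whose cargo was driven by a myosin light chain (MLC) promoter, at 8 weeks of age. The cargo was either luciferase, which served as the control protein, or the amino-terminal part of histone deacetylase 4 (HDAC4, amino acids 1 to 201), here called HDAC4-NT. Surgery followed 4 weeks later and the hearts were taken 4 weeks after surgery. Transverse aortic constriction (TAC) narrows the aorta and loads the heart with pressure, and sham surgery omits the constriction. The groups were sham with luciferase, TAC with luciferase and TAC with HDAC4-NT. No sham group received HDAC4-NT, so its effect in an unloaded heart was not measured here. The number of arrays limits the precision, and the median standard error of a log2 fold change between 2 groups was 0.07.

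The first principal component held 55.3% of the variance and separated the sham hearts from both TAC groups. The second held 20.01% and separated TAC-luciferase hearts 2 and 3 from the rest. TAC-luciferase heart 1 correlated more closely with the HDAC4-NT hearts (Pearson r across genes 0.991 to 0.992) than with the other hearts of its own group (0.986 to 0.987). Genes are not independent replicates, so these correlations only describe the arrays. The Y-linked genes Eif2s3y, Kdm5d and Uty had signal on all 9 arrays, with lowest log2 values of 6.97, 6.30 and 7.32, while Xist, which is expressed from the inactive X chromosome, stayed between 5.22 and 5.27.

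**Figure D1:**
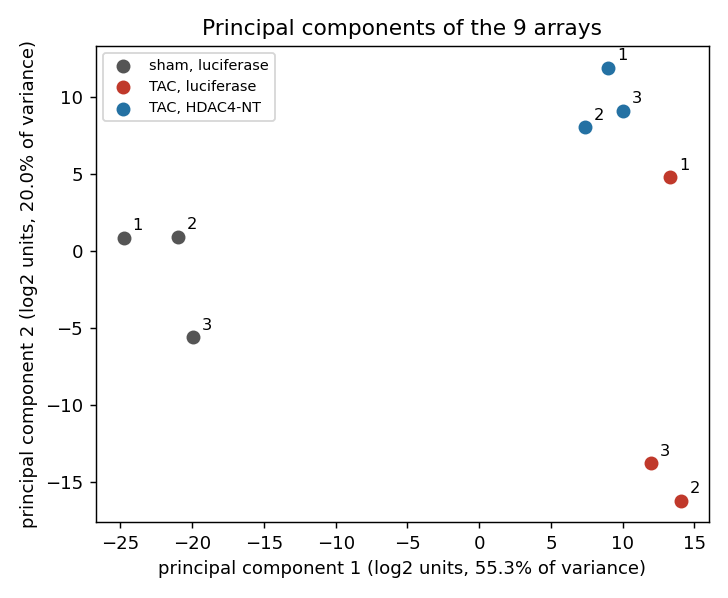
Principal components 1 and 2 of the 9 arrays (log2 units on both axes), each point an array numbered by its replicate and coloured by group. The sham arrays lie apart on component 1, and TAC-luciferase array 1 lies at 4.79 on component 2, between the HDAC4-NT arrays (8.05 to 11.9) and TAC-luciferase arrays 2 and 3 (-16.2 and -13.8).

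The comparison of TAC with sham surgery, both with luciferase, asks what pressure load changed in the heart. Matrix genes were among those that rose most. Thbs4, a matricellular protein of the thrombospondin family, was 12.6-fold higher (log2 fold change 3.66, SE 0.16), and Postn, which encodes periostin, was higher by 3.39 log2 units (SE 0.12). Cilp, Mfap5, Ccn2 and Mfap4 rose 7.71-fold, 6.65-fold, 6.41-fold and 6.36-fold. Sprr1a, a small proline-rich stress protein, rose by 3.59 log2 units and Serpina3n, a serine protease inhibitor, by 3.34. Among the genes that fell, Ces1d, a carboxylesterase, was 5.43-fold lower and Ucp3, a mitochondrial carrier, 3.13-fold lower. The inward rectifier potassium channel genes Kcnj3 and Kcnj2 were 2.74-fold and 2.72-fold lower, and Aqp7, a glycerol channel, and Tbc1d4, which takes part in insulin-stimulated glucose uptake, were 2.70-fold and 2.55-fold lower. The largest falls also included Lgals4, Stard10, Pla2g5 and Asb15, by 2.57-fold to 2.89-fold.

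All 39 extracellular matrix genes measured rose (39 adjusted over the list alone), with a median log2 fold change of 1.32 and an adjusted p of 4.37e-07 (fry). Col8a1 rose by 1.99 log2 units, Tgfb2 by 1.92, Col1a1 by 1.44 and Bgn by 1.32. Of the 15 fetal and hypertrophy genes, 14 rose (14 adjusted over the list alone), with an adjusted p of 6.07e-06. The ventricular level of Nppa, which encodes a natriuretic peptide of the atria and the fetal ventricle, is a common marker of load. These arrays measured whole hearts, so the values here can include atrial tissue. Nppa rose 4.10-fold, from a log2 mean of 11.12 ± 0.16 to 13.15 ± 0.08 (SD, n = 3), Nppb by 1.21 log2 units and Myh7, the fetal myosin heavy chain of the mouse ventricle, by 2.42. Of 29 fatty acid oxidation genes, 26 fell (26 adjusted over the list alone), with a median of -0.54 and an adjusted p of 2.10e-06. Acaa2 fell by 0.99 log2 units, Acot2 by 0.82 and Mlycd by 0.69. These 3 lists also passed camera with an estimated correlation.

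Another 9 lists passed fry and not camera with an estimated correlation. Of 29 oxidative phosphorylation genes, 18 fell (19 adjusted over the list alone; adjusted p = 0.0572 with an estimated correlation), among them Ndufa9, by 0.57 log2 units. Of 17 ion channel and gap junction genes, 12 fell (12 adjusted over the list alone; adjusted p = 0.108 with an estimated correlation), including Kcnd2, a subunit of the transient outward current, by 1.27. Of 18 immediate early genes, which respond to a stimulus within minutes, 14 rose (16 adjusted over the list alone; adjusted p = 0.169 with an estimated correlation). Atf3, a stress-induced transcription factor, rose by 2.39 log2 units and Btg2, an antiproliferative gene, by 1.35. Of 18 cell cycle genes 14 rose (17 adjusted over the list alone), of 17 macrophage and myeloid markers 8 rose (10 adjusted over the list alone), and of 14 fibroblast markers 6 rose and 1 fell (6 and 2 adjusted over the list alone). Each of these 3 lists had an adjusted p of 0.169 with an estimated correlation. Ccnd2 rose by 1.05, C1qa by 0.87, and the fibroblast genes Meox1 and Serpinf1 by 1.86 and 1.79 log2 units. Of 13 cytokine and acute-phase genes, 5 rose and 1 fell (6 and 1 adjusted over the list alone; adjusted p = 0.235 with an estimated correlation). In TAC-HDAC4-NT against sham the immediate early list did not pass (2 of 18 higher, fry adjusted p 0.641). Neither did the cytokine list (2 of 13 higher, fry adjusted p 0.223). Both lists thus passed against sham in TAC-luciferase only, and whether load caused their rise was not tested.

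The remaining lists that passed concern HDAC4 and its partners. Of 17 genes described as MEF2 targets, 7 rose and 2 fell (8 and 2 adjusted over the list alone; adjusted p = 0.169 with an estimated correlation). MEF2 is a transcription factor family that class IIa histone deacetylases repress. The list includes Nr4a1, an orphan nuclear receptor, which rose by 2.57 log2 units, and Myh6, the adult myosin heavy chain, at -0.23 (adjusted p 0.0271, and 0.103 under cyclic loess scaling). Myh6 lost its call without any 1 of 4 arrays, sham hearts 2 and 3 and TAC-luciferase hearts 2 and 3, with adjusted p-values up to 0.095. Of 10 class IIa HDAC, MEF2 and partner genes, 2 fell, Hdac5 by 0.42 and Mef2a by 0.25 log2 units (1 fell adjusted over the list alone; adjusted p = 0.146 with an estimated correlation). Mef2a lost its call without any 1 of 8 arrays (adjusted p up to 0.0966). The mouse's own Hdac4 probe set stood at -0.16 (SE 0.06, adjusted p 0.1).

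In the hexosamine pathway list, which makes the sugar donor for O-GlcNAc modification of proteins, Gfpt2 rose by 1.27 log2 units and Oga, which removes the modification, fell by 0.45. The other 12 of its 14 measured members did not pass (1 higher and 1 lower adjusted over the list alone), and the list's adjusted p was 0.635. Members of the glycolysis and glucose uptake list went both ways, 5 up and 5 down of 19 (5 and 5 adjusted over the list alone), with a median of -0.02, a mean of 0.09 and an adjusted p of 0.635. Slc2a1, the basal glucose transporter, rose by 1.52 and Pfkp by 1.40, while Slc2a4, the insulin-responsive transporter, fell by 0.69. The unfolded protein response list had 7 of 17 members lower, Hspa5 by 0.53 and Herpud1 by 0.66, and Atf4 higher by 0.47, with an adjusted p of 0.0794 (1 higher and 8 lower adjusted over the list alone). The interferon response list (4 of 13 higher), calcium handling (3 higher and 4 lower of 23, with Atp2a2 at -0.16 and an adjusted p of 0.0535), adult sarcomere (2 higher and 2 lower of 20) and the circadian clock (2 higher and 2 lower of 15) did not pass either. The adult sarcomere list had a median of 0.02 and a mean of 0.02, with 11 of 20 members above 0, while fry gave it the direction down (adjusted p 0.96). Under cyclic loess scaling fry gave up and the list passed (adjusted p 0.03). Adjusted over the list alone, these 4 lists had 4 genes higher, 3 higher and 6 lower, 1 higher and 2 lower, and 2 higher and 3 lower. Among markers of other cells, the endothelial (2 higher and 2 lower of 16), smooth muscle and pericyte (1 and 1 of 10), atrial (1 and 2 of 7) and epicardial (1 and 0 of 5) lists did not pass. Adjusted over the list alone, they had 3 and 2, 1 and 1, 1 and 2, and 2 and 0 genes higher and lower. Neither did the lymphocyte, adipocyte, skeletal muscle and erythroid lists, with list adjusted p-values of 0.149, 0.52, 0.81 and 0.52.

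By limma with a Benjamini-Hochberg adjusted p under 0.05, 3283 of 12597 genes changed, 1405 higher and 1878 lower, and 211 of them by at least 2-fold. Under cyclic loess scaling 1661 were higher and 1496 lower (52.6% higher, against 42.8%), so which direction holds more genes depends on the scaling. The 2 groups did not overlap for 37.4% of the genes, where chance gives 10%. Thbs1, 9.64-fold higher, lost its call without sham heart 1 (adjusted p 0.0534). Its log2 fold change of 3.27 was 4.13 without TAC-luciferase heart 1 (9.27, against 11.95 and 11.75) and 4.03 without sham heart 3 (9.23, against 7.01 and 6.91). Nr4a1 stood at 3.55 without TAC-luciferase heart 1, and it lost its call without any 1 of sham hearts 1 and 3 and TAC-luciferase hearts 2 and 3, with adjusted p-values up to 0.0779.

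**Figure D2:**
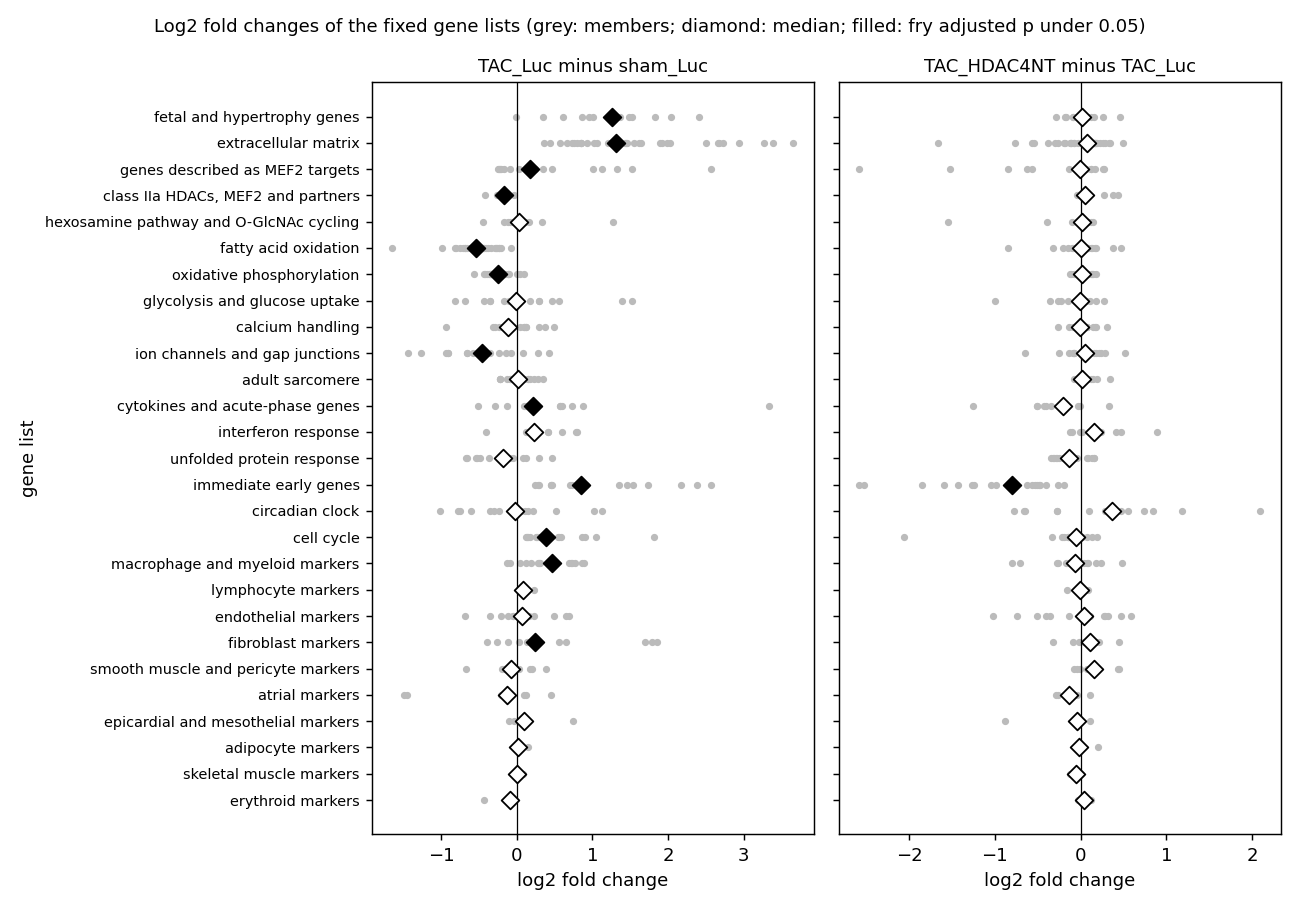
Log2 fold changes (horizontal axes) of the 27 tested gene lists, TAC-luciferase minus sham on the left and TAC-HDAC4-NT minus TAC-luciferase on the right. Grey points are genes, diamonds list medians, and filled diamonds mark a fry adjusted p under 0.05, which 12 lists reached on the left and 1 on the right.

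The comparison of the TAC groups, HDAC4-NT against luciferase, asks what the HDAC4 fragment changed in the loaded heart. Atf3 differed most among the genes that passed. It was 5.74-fold lower with HDAC4-NT (log2 fold change -2.52, SE 0.23, adjusted p 0.00667), at a log2 mean of 6.07 ± 0.30 against 8.59 ± 0.50 (SD, n = 3) and 6.21 ± 0.18 in sham. Btg2 was 2.36-fold lower (adjusted p 0.00423). Ero1a, which oxidises proteins in the endoplasmic reticulum, was 1.92-fold lower and Slc2a1 1.99-fold lower. Otud1, a deubiquitinase, and Gadd45g, a stress-inducible gene, were 2.61-fold and 2.06-fold lower, and Arid5a, Tent5a, Anp32a, Shb and Klf4 were lower by 0.53 to 0.82 log2 units. Cd200, a membrane glycoprotein that restrains myeloid cells, was 2.00-fold higher. Efna1, an ephrin ligand, Olfr558, an olfactory receptor gene, and Pxdn, a peroxidase of the matrix, were higher by 0.74, 0.74 and 0.65 log2 units. Lrrc14b, Arhgap32, Col8a1, Nos2, Nav3 and Pik3c2b were higher by 0.43 to 0.56.

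The immediate early genes were the 1 list of 27 that passed in this comparison (fry adjusted p 0.0212, median -0.80; adjusted p = 0.25 with an estimated correlation). Atf3, Btg2 and Klf4 fell (16 of 18 members adjusted over the list alone), and all 18 measured members had a log2 fold change below 0. The list's call was lost without any 1 of 6 arrays, sham hearts 1 and 2, each of the HDAC4-NT hearts and TAC-luciferase heart 2, with adjusted p-values up to 0.101. Nr4a1 stood at -2.58 (SE 0.68, adjusted p 0.125) and Gfpt2 at -1.55 (SE 0.29, adjusted p 0.0611). TAC-luciferase heart 1 lay far below hearts 2 and 3 for Nr4a1, at 7.66 against 10.56 and 10.65. It also did so for Gfpt2, at 7.66 against 8.80 and 8.70, and without it both genes passed (adjusted p 0.00027 and 0.00123), Nr4a1 at -3.56. Heart 1 correlated more closely with the HDAC4-NT hearts than with its own group, so leaving it out favours such calls. Without it 697 genes passed, against 32 with all hearts, so these 2 calls do not replace the result with all hearts.

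The fetal and hypertrophy genes did not differ detectably between the TAC groups. The adjusted p of that list was 0.788, and Nppa stood at 0.16 (SE 0.08), Nppb at -0.17 (SE 0.12), Myh7 at -0.09 (SE 0.18) and Acta1 at 0.12 (SE 0.22). Among 39 extracellular matrix genes, Col8a1 was higher with HDAC4-NT by 0.49 log2 units (3 higher and 2 lower adjusted over the list alone). The list's median was 0.07, its mean -0.04 and its adjusted p 0.63, and Col1a1 stood at 0.18 (SE 0.09). The fatty acid oxidation and oxidative phosphorylation lists had adjusted p-values of 0.784 and 0.677. The class IIa HDAC, MEF2 and partner list and the MEF2 target list had 0.129 and 0.435. Adjusted over the list alone, they had 1 higher and 0 lower, and 1 higher and 5 lower. The MEF2 target list had a median of -0.01 and a mean of -0.31. It was 1 of 9 lists of 27 that passed the fry test for change in either direction, so this is not particular to MEF2 targets (adjusted p 0.00103, against 0.000512 for the extracellular matrix and for the smooth muscle and pericyte lists). The other lists that passed it were glycolysis, immediate early genes, the unfolded protein response, endothelial markers, cytokines and the clock. Gfpt1, Ogt, Oga and Stim1 lay between -0.10 and 0.14, none past the threshold. The mouse's own Hdac4 stood at -0.02 (SE 0.06). Where its probes lie is not given in the sources used here, so this checks nothing about the delivered fragment. The circadian clock list had a median of 0.36 and an adjusted p of 0.0698, with Dbp at 2.10 (SE 0.48, adjusted p 0.0877). Dbp lay at 8.68 in TAC-luciferase heart 1, against 7.16 and 6.66 in hearts 2 and 3, and without heart 1 it stood at 2.69 (adjusted p 0.00275). Leaving heart 1 out favours such a call, as for Nr4a1. A mean difference between clock activator and output genes ran from -1.70 to -1.05 in the HDAC4-NT hearts and from -0.74 to 0.98 in the TAC-luciferase hearts. The mean of 4 atrial genes was 5.98, 6.23 and 8.07 in TAC-luciferase hearts 1, 2 and 3 and 5.94 to 6.94 in the HDAC4-NT hearts.

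In limma, 32 of 12597 genes passed, 18 higher and 14 lower (43.5% higher of 23 genes under cyclic loess scaling, against 56.2%), and 1807 had an unadjusted p under 0.05. The groups did not overlap for 20.4% of the genes, where chance gives 10%. The count ranged from 1 without HDAC4-NT heart 1 or 2 to 697 without TAC-luciferase heart 1, it was 0 with only the 6 arrays of these groups (1868 genes at an unadjusted p under 0.05) and 0 with the clock genes' index as a covariate (805), and 827 with weighted arrays. Among the 20 genes named by size of change, Btg2 alone kept its call without each of the 9 arrays in turn (highest adjusted p 0.0429), and Klf4, named from its list, lost it without any 1 of 7.

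**Figure D3:**
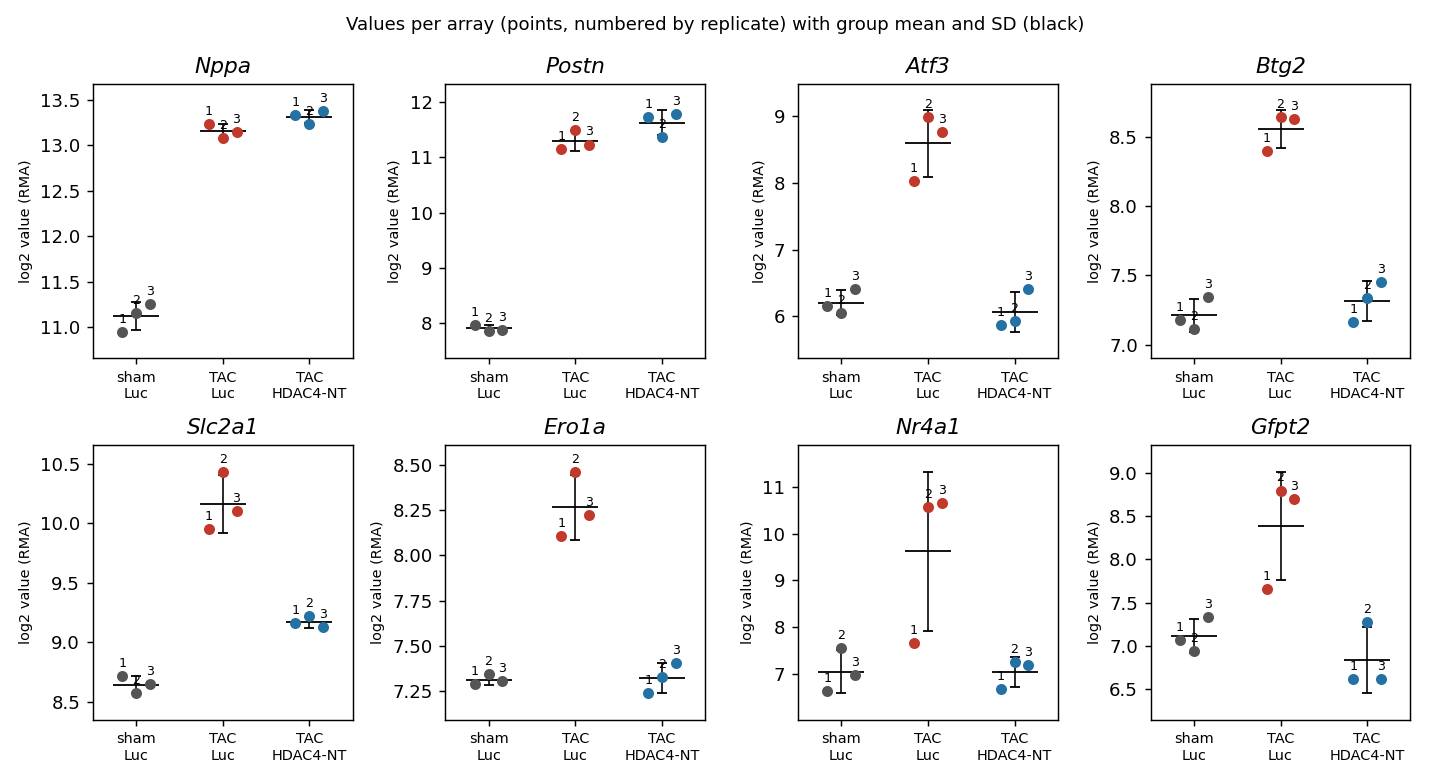
RMA log2 values (vertical axes) of 8 genes in each of the 9 hearts, points numbered by replicate, with group mean and SD in black. The vertical axes do not start at 0. For Atf3, Btg2, Slc2a1 and Ero1a all TAC-luciferase hearts lie above all HDAC4-NT hearts, and for Nr4a1 TAC-luciferase heart 1 (7.66) lies near the HDAC4-NT hearts (6.68 to 7.26).

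The genes that differed between the TAC groups were set against the response to TAC itself. Of the 14 genes lower with HDAC4-NT, 12 were higher in TAC-luciferase than in sham, where independent lists would share 1.56. Of the 18 higher with HDAC4-NT, 12 were lower in TAC-luciferase than in sham, where independent lists would share 2.68. Col8a1 was higher in both comparisons and the other 7 did not pass in TAC-luciferase against sham. The TAC-luciferase arrays enter both comparisons with opposite signs, so their chance values alone give opposite directions. Over all genes the correlation of the log2 fold changes was -0.42, and -0.50 for simulated unchanged groups. Genes of opposite sign made up 61.8%, against 66.7% simulated. Neither the correlation nor this share went beyond the simulated value. The simulation left sham unchanged too, whereas 3283 genes differed between TAC-luciferase and sham in the data. Such differences add spread that the simulated groups lack, so the correlation and the share cannot be judged against these values. The covariance went beyond the simulated value, at -0.0239 against -0.00427. The simulated genes were independent, with the same spread in every group. They do not hold the split within the TAC-luciferase group, so the simulated covariance may be understated. The counts of shared genes were set only against independent lists. Part of the excess in the covariance and in these counts may come from the shared arrays, which are too few to split.

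**Figure D4:**
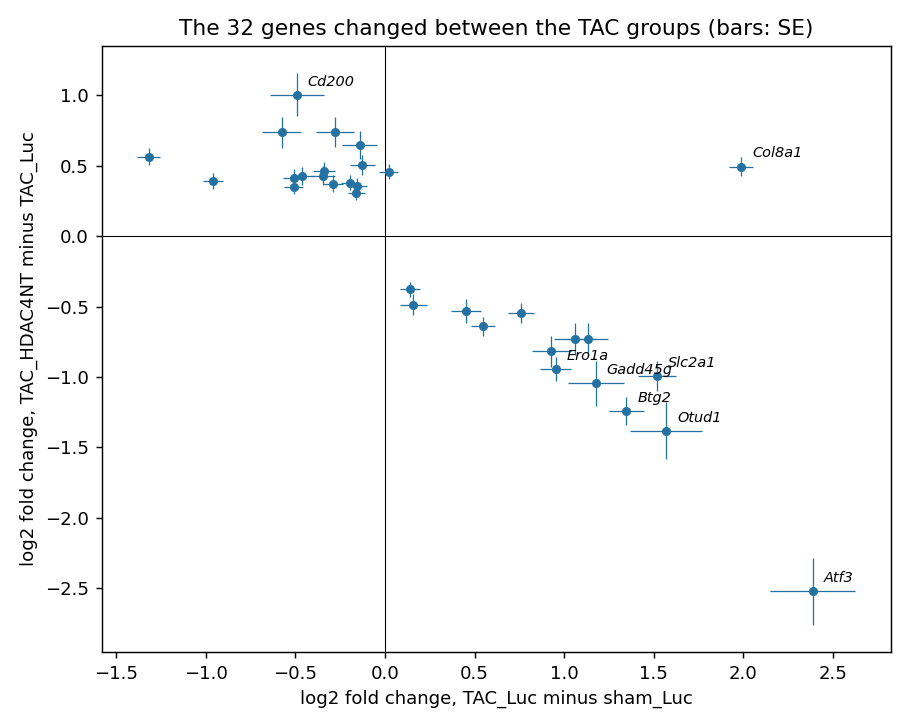
Log2 fold change of the 32 genes changed between the TAC groups, TAC-HDAC4-NT minus TAC-luciferase (vertical axis), against TAC-luciferase minus sham (horizontal axis), with standard errors as bars. Atf3 lies at 2.39 and -2.52, and Col8a1 is positive on both axes (1.99 and 0.49).

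A score of the whole TAC response, scaled over 3544 genes so that 0 is sham and 1 the mean of the TAC groups, was 1.02 ± 0.04 in TAC-luciferase and 0.98 ± 0.04 in TAC-HDAC4-NT (SD, n = 3). The difference of -0.05 had an exact two-sided permutation p of 0.3, where 0.1 is the smallest that 3 against 3 allow. The difference was -0.144 without TAC-luciferase heart 1, -0.074 without TAC-luciferase heart 3, -0.024 without sham heart 1 and -0.0114 without HDAC4-NT heart 2. It was -0.0125 with the 500 genes of smallest p, so its size depends on single hearts and on the choice of genes. With genes and weights from TAC-luciferase against sham alone it was -0.194. That choice favours a higher score in TAC-luciferase by construction, because the same arrays pick the genes.

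The comparison of TAC with HDAC4-NT against sham with luciferase combines surgery and virus. Thbs4 (3.82 log2 units), Postn (3.72), Sprr1a (3.59), Cilp (3.05) and Mfap5 (2.84) rose most, and Ces1d (-2.09), Stard10 (-1.63), Lgals4 (-1.47) and Pla2g5 (-1.46) fell most. The small nucleolar RNA gene Snord14e, lower by 1.46, lost its call without 1 of 4 arrays, sham hearts 2 and 3 and HDAC4-NT hearts 1 and 2 (adjusted p up to 0.0873). All but 1 of 39 matrix genes rose (38 adjusted over the list alone), 14 of 15 fetal and hypertrophy genes rose (14 adjusted over the list alone) and 24 of 29 fatty acid oxidation genes fell (26 adjusted over the list alone). These 3 lists also passed camera with an estimated correlation.

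Another 10 lists passed fry and not camera with an estimated correlation. Of 17 unfolded protein response genes, 11 fell (1 higher and 11 lower adjusted over the list alone; adjusted p = 0.41 with an estimated correlation), Hspa5 by 0.74, Herpud1 by 0.75 and Sdf2l1 by 0.77 log2 units. Of 13 interferon response genes, 7 rose (10 adjusted over the list alone; adjusted p = 0.407 with an estimated correlation), with Oasl2 at 0.84 and Irf7 at 0.68. Irf7 lost its call without HDAC4-NT heart 1 (adjusted p 0.052). The interferon call was lost without 1 of 4 arrays, sham hearts 1 and 2 and HDAC4-NT hearts 1 and 3, with adjusted p-values up to 0.0791. Of 15 clock genes, 4 rose and 1, Arntl, fell by 0.81 (6 and 3 adjusted over the list alone; adjusted p = 0.407 with an estimated correlation). Arntl lost its call without sham heart 3 or HDAC4-NT heart 1 (adjusted p up to 0.0565). The clock call was lost without any 1 of 7 arrays, all but HDAC4-NT heart 2 and TAC-luciferase heart 1, with adjusted p-values up to 0.124. The oxidative phosphorylation list (17 of 29 lower) had an adjusted p of 0.0572 with an estimated correlation and the ion channel list (12 of 17 lower) 0.0897. The fibroblast (8 higher, 1 lower of 14), macrophage (10 higher, 1 lower of 17) and cell cycle (10 of 18 higher) lists had adjusted p = 0.168, 0.286 and 0.345 with an estimated correlation. The MEF2 target list (5 higher, 2 lower of 17) and the class IIa HDAC list (1 higher, 2 lower of 10) had 0.463 and 0.407. Adjusted over the list alone, 19 oxidative phosphorylation and 12 ion channel genes were lower, 8 fibroblast markers were higher and 3 lower, 12 macrophage markers were higher and 1 lower, 12 cell cycle genes were higher, and the 2 HDAC4-related lists had the same counts. Of 18 immediate early genes, 2 rose, Ier3 by 0.65 and Ccn1 by 0.90 (2 adjusted over the list alone), and that list did not pass (adjusted p 0.641). Nr4a1 stood at -0.01 (SE 0.68) and Gfpt2 at -0.28 (SE 0.29).

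In limma, 2872 of 12597 genes passed, 1326 higher and 1546 lower. Under cyclic loess scaling 1468 were higher and 1337 lower (52.3% higher, against 46.2%). Of the genes that passed, 942 were higher and 1257 lower in both TAC groups than in sham, where independent lists would share 148 and 230. Cd200 and Lmo4 passed in opposite directions. The correlation of the changes against sham was 0.83 and 0.50 for simulated unchanged groups, and the covariance was 0.0782 against 0.00426. The sham arrays enter both comparisons, so part of the excess may come from them.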

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

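The tests of TAC-luciferase hearts 2 and 3, of the time of day, of the virus and of the atrial share, and the look at the TAC score of heart 1, were chosen after the results they bear on were seen. Of 986 probe sets with no gene name here, 567 passed the filter and 120 of these changed in TAC-luciferase against sham, 54 of them higher. That is 21.2%, against 26.1% of the named genes tested, and these probe sets have no part in the comparisons of named genes. In TAC-HDAC4-NT against TAC-luciferase limma called 0 of them, with 67 at an unadjusted p under 0.05.

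The immediate early genes passed as a list, lower with HDAC4-NT than with luciferase after TAC, with a median log2 difference of -0.80. The call does not hold with an estimated correlation (adjusted p 0.25) or without any 1 of 6 arrays, and 3 of 18 members passed over all genes. With TAC-luciferase heart 1 as the only heart of its group the median was -0.467 and 17 of 18 members were lower. This rests on 1 heart, so whether hearts 2 and 3 alone carry the difference cannot be told. With the clock index as a covariate the median was -0.253 and 17 of 18 were lower (fry p 0.0284), and because the index lies higher in every TAC-luciferase heart than in every HDAC4-NT heart, a different clock phase at harvest and the group cannot be told apart. Of 24 hypoxia-responsive genes, 21 were measured and 17 were lower with HDAC4-NT. The median was -0.22 (unadjusted fry p 0.0374, smallest single adjusted p 0.0568, for Bnip3). The list was written after the fall of Slc2a1 and Ero1a was seen (both left out) and before it was tested as a list. Its Hk2, Pdk1, Pfkfb3 and Loxl2 also belong to the fixed glycolysis and matrix lists, which were tested too. Less oxygen shortage in that group, in life or during dissection, may give such lower values. For Plod2, Pfkfb3 and Hk2, TAC-luciferase heart 1 (7.63, 5.75 and 8.85) lay within the HDAC4-NT hearts. For Bnip3, Adm and Vegfa all TAC-luciferase hearts lay above all HDAC4-NT hearts. Camera and leaving out single arrays were not run for this list. An effect of HDAC4-NT on the immediate early genes stays open, since it has no measure apart from the group.

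No clock gene of 15 passed between the TAC groups (smallest adjusted p 0.0611, for Per3), and neither did the list (adjusted p 0.0698, and 0.288 with an estimated correlation). The medians of the 6 output genes (0.79, all higher with HDAC4-NT) and of the 3 activator genes (-0.65, all lower) lay 1.44 apart, as a different time of day at harvest may give. These genes were picked after their values were seen, so the test cannot count for that explanation, and harvest times are not given in the sources used here. The clock index ranged 2.48 times as widely within TAC-luciferase as in the wider of the other groups. A spread within that group does not exclude an effect of the virus, so the time of day and the virus cannot be told apart here.

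TAC-luciferase heart 1 lay near the HDAC4-NT hearts. Hearts 2 and 3 of its group differed by 1.84 log2 units in the mean of the atrial genes, and heart 2 lay within the range of the HDAC4-NT hearts. A different atrial share thus does not go with the split in these values. The bound for it was written after they were seen and rests on heart 2, so an atrial share is not excluded. On 697 genes called without it, heart 1 lay at 0.248 on a line from 0 (HDAC4-NT) to 1 (hearts 2 and 3), above the HDAC4-NT hearts (-0.06 to 0.05) and under the bound of 0.25 set beforehand for arguing against a mislabelled array, and sham heart 3 lay at 0.27. On the 244 of these genes past an adjusted p of 0.01, heart 1 lay at 0.218, under the bound and above the HDAC4-NT hearts (-0.05 to 0.04). The HDAC4-NT hearts helped to pick these genes and set the 0 of the line, and heart 1 did not. Their narrow range is thus partly built in, and any array left out may fall outside it. On the score of the whole TAC response heart 1 was not low, at 1.07 the highest of the 9 arrays (1.03 and 0.98 in hearts 2 and 3), though the score's genes were picked with this heart included. Its Nppa (13.24) and Nppb (12.59) were the highest of its group, but its Nppa lay within the HDAC4-NT hearts (13.24 to 13.38) and does not separate it from them. The first number of the sample code was 8 for heart 1 and 9 for hearts 2 and 3, and what it marks is not given in the labels. The bound cannot tell apart a mislabelled array, a heart that differs from its group in these genes, and whatever that number marks.

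Splits of the 6 arrays of a comparison into 3 and 3 number 10, too few for a share under 0.05. The real split called 3283 genes in TAC-luciferase against sham and the highest other split 3. In TAC-HDAC4-NT against TAC-luciferase it called 32 and the highest other 1, and in TAC-HDAC4-NT against sham 2872 and 0. In each comparison 1 split, the real one, gave as many genes.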

How the results depend on the processing

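The clock and atrial covariates, and leaving out TAC-luciferase hearts 2 and 3 together, were chosen after seeing the data. The counts against sham stayed within 1.5 times of 3283 and 2872 in all settings except an adjusted p under 0.01 (1748 and 1579) and a minimum of 1.5-fold (775 and 610), which call fewer by construction. Leaving out 1 array gave 2435 to 3230 genes for TAC-luciferase and 1921 to 3161 for TAC-HDAC4-NT. The 32 genes between the TAC groups became 10 without a filter, 103 with the stricter filter, 75 with the trended and robust prior, 827 with array weights (weight 0.479 for TAC-luciferase heart 1), 0 with only these 2 groups, 3 and 297 at adjusted p under 0.01 and 0.10, 14 with the minimum fold, 0 with the clock covariate, 7 with the atrial covariate and 10 without TAC-luciferase hearts 2 and 3. In limma, 1868 and 805 genes had an unadjusted p under 0.05 in the settings with 0 calls. With only 2 groups, 4 residual degrees of freedom remain. Whether this caused the fall to 0 was not tested, and neither were the causes of the other changes. Leaving out 1 array gave 16, 6 and 7 genes without sham hearts 1, 2 and 3, 1, 1 and 9 without HDAC4-NT hearts 1, 2 and 3, and 697, 4 and 12 without TAC-luciferase hearts 1, 2 and 3. With the replicate number as a block the count was 106, with 30 of the 32 genes among them. The hearts were not treated as paired by number, since 2 of 9 same-numbered pairs had a correlation of deviations over 0.1 (range -0.123 to 0.199) and 0 arrays correlated best with their own number in both other groups. With the first number of the sample code as a random block, the count was 177 (estimated correlation -0.113). What this number means is not given in the labels. It was 12 in all sham hearts and 3, 4 and 4 in HDAC4-NT hearts 1, 2 and 3. In TAC-luciferase hearts 1, 2 and 3 it was 8, 9 and 9. No number occurs in more than 1 group, so whatever it marks cannot be told apart from the group. Of 26 list calls, 6 held in camera with an estimated correlation and 23 to 26 without 1 array. The adult sarcomere list, not called in TAC-luciferase against sham, turned from down to up in fry under cyclic loess (adjusted p 0.03002, and 0.96 before, with a median of 0.02), and the cause was not tested. The score difference (TAC response score, TAC_HDAC4NT against TAC_Luc) was below 0 in every setting run, lowest at -0.1936 and highest at -0.01144. The lowest came with genes picked from TAC-luciferase against sham alone, a choice that favours this direction by construction. Of the 50 genes named by size of change, 30 to 50 stayed past the threshold without 1 array. The mean of several probe sets per gene was not run, since each gene has 1. Signal over background is not in the table, so what it limits was not measured.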

Other observations

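The hypoxia-responsive list was written after other results were seen. Cdkn1a, which encodes a cell cycle inhibitor, stood at -2.06 log2 units with HDAC4-NT against TAC-luciferase (SE 0.50, adjusted p 0.102), with log2 values of 10.06, 11.56 and 11.64 in the TAC-luciferase hearts and 8.86 to 9.15 in the HDAC4-NT hearts. Lcn2, an acute-phase iron-binding protein, stood at -1.25 (SE 0.30, adjusted p 0.1), Wt1, an epicardial transcription factor, at -0.88 (SE 0.24, adjusted p 0.137) and the endothelial tight junction gene Cldn5 at -1.02 (SE 0.20, adjusted p 0.0611). The pericyte genes Pdgfrb and Cspg4 stood at 0.45 and 0.43 (SE 0.07 and 0.07), with adjusted p-values of 0.0519 and 0.0532. None of these passed.

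In the hypoxia-responsive list, 16 of 21 measured genes were higher in TAC-luciferase than in sham (median 0.22, fry p 0.048), and 7 of them passed limma, with 2 others lower. Plod2, a collagen-modifying enzyme, stood at 1.14 log2 units and Bnip3, a mitochondrial stress gene, at 0.53. Ddit4 stood at -2.29 (SE 0.78, adjusted p 0.227) in TAC-HDAC4-NT against TAC-luciferase, and at -3.42 without TAC-luciferase heart 1 (adjusted p 0.000449). Leaving that heart out favours such a call. The difference rests on TAC-luciferase hearts 2 and 3, at 9.84 and 9.91, while heart 1 lay at 6.49, within the HDAC4-NT hearts (6.30 to 6.75).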
